A study of Mus musculus with 12 samples.

How the data were processed

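Bone-marrow-derived macrophages of C57BL6/J and Balb/cAnNCrl mice, called C57BL6 and Balb/c from here on, were profiled on 12 Agilent whole-genome mouse arrays labelled with Cy3 alone. Each strain gave 2 untreated (mock) samples, 2 samples after 4 h and 2 samples after 18 h of IL-4 (interleukin-4) at 10 ng/ml. Per the sample descriptions the marrow came from mice 8 to 12 weeks old, each sample was a pool of 2 males and 1 female, and 1 µg of RNA was labelled. Cells were grown with CSF1, changed to fresh medium on day 5, replated on day 6 and given IL-4 from day 7. Mock cells were incubated for 18 h, so the 4 h samples had no mock of their own time.

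The deposited scanner text files of each array, written by Agilent Feature Extraction 9.5.1.1 per the submitters' processing notes, held the processed green signal as intensity in linear scanner units, per the file headers. The deposited values held a linear ratio for each probe. The authors did not state its denominator. The values settled it: each column was the processed signal after scaling, over the mean of the 2 C57BL6 mock arrays. The standard deviation of the log2 difference between the deposited ratios and that rebuilt ratio was at most 0.0045 on any array. Column medians of the deposited ratios ran from 0.936 to 1.132. The fit used the scanner intensity, and the deposited ratios served as an alternative.

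Control spots and spots marked as non-uniform or as population outliers in the scanner files were left out. Intensities were put on a log2 scale, spots of the same probe were averaged, and the 75th percentile of each array was subtracted. No background correction was applied beyond the one already inside the processed signal. Of 41174 probes, 27373 were kept because the scanner software called them well above background on both arrays of at least 1 group. Of the kept probes, 17629 took their gene name from the transcript accession, 3978 from a current symbol and 1871 from an older symbol, through the RefSeq annotation of GRCm38.p6. The other 3895 kept the name of the scanner file. For each gene the kept probe with the highest mean over the 12 arrays was tested, which gave 18427 genes.

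Group means of the 6 groups were fitted with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), followed by empirical Bayes moderation. The residual degrees of freedom were 6 and the prior degrees of freedom 2.04. The 8 comparisons were IL-4 at 4 h and at 18 h against mock within each strain, 18 h against 4 h of IL-4 over both strains, Balb/c against C57BL6 in mock, and the strain difference of the IL-4 effect at each time. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, with no fold limit. Errors beside a log2 change are standard errors from limma.

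Named genes followed a rule set before the values were examined: per comparison, among called genes with a gene symbol rather than a clone or predicted name and with replicate values that did not overlap between the groups, those with the largest positive and negative log2 change among genes well above background on every array of both groups, up to 8 on each side for IL-4 and strain and up to 6 for 18 h against 4 h, up to 4 on each side among genes near background, and up to 6 members of each gene list, called ones first. A gene that was not well above background on any array of one side was near background there. Its change is a bound, written as at least that many fold, measured from the lowest log2 level that the scanner software called well above background on each array, or from the gene's own level there when that was higher. A set of genes was also fixed in advance and is reported whatever the outcome: Arg1, Irf4, Il4ra, Nnt and H2-Ea.

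The 30 gene lists were written from general knowledge before the values were examined and held 426 genes. They covered alternative activation markers, IL-4 receptor signalling, transcription factors of IL-4-primed macrophages, inflammatory genes, Toll-like receptor signalling, interferon response, MHC class II, cell cycle, cholesterol synthesis, fatty acid oxidation, glycolysis, oxidative phosphorylation, lysosome, cell fusion, chemokines, arginine and polyamines, macrophage identity, immediate-early genes and ribosomal proteins. Markers of T cells, B cells, erythroid cells, mast cells and basophils, neutrophils, eosinophils, dendritic cells, stromal cells and megakaryocytes, sex-linked genes and a strain check completed them. Lists with at least 4 tested genes, 28 in all, were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data and with fry, adjusted over the lists within each comparison by Benjamini-Hochberg. Counts adjusted over a list alone used Benjamini-Hochberg on the p-values of that list's genes only. List means used the fitted log2 change of every member, also of those near background, so they are not exact sizes where such members enter.

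Replicate numbers were checked as pairs, since the series text describes independent experiments with different littermates. Between groups of the same strain, the deviations of replicate 1 from the group mean correlated at 0.62 (mock and 4 h), 0.30 (mock and 18 h) and 0.16 (4 h and 18 h) in C57BL6, and at 0.50, 0.31 and 0.65 in Balb/c. Across strains they ran from -0.31 to 0.14. The fit over 6 groups ignored this pairing, and a fit with replicate within strain as a block is given beside each IL-4 count. Samples of the same replicate often shared a slide, which may add to these correlations. The arrays lay on 3 slides scanned on the same day.

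Alternatives fixed before the data were examined were median and quantile scaling, normexp background correction with an offset of 50, the deposited ratios, no background filter, a filter asking for all 12 arrays, every kept probe, a mean-variance trend, a fit on only the arrays compared, replicate blocks within and across strains, a slide block, and leaving out each array in turn. Chosen after seeing the data were array quality weights, and a local background subtraction from the mean signal with an offset of 50. The mean signal and the local background were used only for that alternative and for the normexp correction, which thus also differ from the main fit in their input signal.

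Overlap between comparisons that share mock arrays was set beside 20 simulations without any change, drawn with the residual spread of the fit, and beside the count for independent lists. Neighbouring genes were counted against 10000 random draws with RefSeq gene order, and a median was bootstrapped 10000 times with 95% limits. In a self-test, 200 genes with known changes were planted in simulated arrays of the same size. Between 2 and 12 of the 106 to 171 genes called were false, and an 8-fold change was recovered in 68% to 96% of the planted genes. An IL-4 effect of 2-fold within a strain was recovered in 14% to 20%, and a 2-fold difference between the untreated strains in 10%. A 2-fold strain difference of the IL-4 effect was recovered in 4% at 4 h and 2% at 18 h. Figures were drawn with matplotlib 3.10.9.

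The deposited protocol mentions lipopolysaccharide, but no deposited sample carries that label and none was analysed. The genome build behind the array annotation was not given, so no coordinates are reported. A single gene of the interferon response list was counted with the list, and its own values are left out.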

Results

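The data were 12 arrays of bone-marrow-derived macrophages, 2 for each of 6 groups: C57BL6 and Balb/c cells left untreated, or given IL-4 for 4 h or 18 h. Each array carried 43379 spots, of which 54.9% to 69.7% were well above background. The 75th percentile of the signal ran from 1196 to 1690 and the median from 70.5 to 125 scanner units, with 0 to 2 saturated spots per array. Replicates correlated at 0.974 to 0.989. The leading principal component held 35.3% of the variance and parted the strains, and the next held 19.4% and followed IL-4. The component after these held 13.5% and parted the arrays of slide 2 (scores 22.5 to 61.7) from the others (-34.0 to 8.0). Each replicate was a pool of several animals, so p-values measure the spread between these samples and not between mice. The number of arrays limits precision.

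The opening question was which genes differed from mock after 4 h of IL-4 in C57BL6 macrophages, with 2 arrays in each group. Arg1, which encodes the arginine-degrading arginase of alternatively activated macrophages, was near background on both mock arrays and rose at least 300.3-fold (limma with Benjamini-Hochberg, adjusted p = 2.1e-04). Retnla, a secreted marker of IL-4-treated macrophages, rose at least 483.3-fold (adjusted p = 0.0053). Feedback inhibitors of cytokine signalling rose as well, Socs1 by 5.22 ± 0.20 log2 (37.3-fold, adjusted p = 8.01e-05) and Cish by 6.40 ± 0.85 (adjusted p = 0.0079). Irf4, a transcription factor downstream of the IL-4 receptor, rose by 4.16 ± 0.56 log2 (adjusted p = 0.0081), from -3.32 and -3.03 on the mock arrays to 0.91 and 1.05. Leaving out any of the 4 arrays ended that call (adjusted p from 0.0539 to 0.0776), with a change of 4.02 to 4.30. Nfkbiz, a nuclear partner of NF-kB that sustains inflammatory transcription, fell by 3.70 ± 0.39 (adjusted p = 0.0039).

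Among genes above background on every array of both groups, others with the largest rises were Rasgrp1 (6.49 ± 0.76 log2, adjusted p = 0.0053), Cdh1 (5.77 ± 0.54, adjusted p = 0.0022), Tmem26 (5.62 ± 0.29, adjusted p = 2.53e-04), Serpina3f (4.94 ± 0.47, adjusted p = 0.0023), Serpina3g (4.92 ± 0.37, adjusted p = 0.001) and Il4i1 (4.88 ± 0.53, adjusted p = 0.0044). Msx3 and Edn1 were near background in mock and rose at least 177.5-fold (adjusted p = 0.001) and 90.7-fold (adjusted p = 0.0039). Jag1 (-3.13 ± 0.37, adjusted p = 0.0053), the iron exporter gene Slc40a1 (-2.94 ± 0.62, adjusted p = 0.0458) and Cxcl10 (-2.81 ± 0.57, adjusted p = 0.0411) fell. Fzd1 dropped to background, at least 4.26-fold (adjusted p = 0.0358). Il4ra, the receptor chain that binds IL-4, rose by 1.80 ± 0.33 log2 (adjusted p = 0.0274). That call did not hold without the background filter (adjusted p = 0.0584) or on only the arrays compared (adjusted p = 0.0755), and leaving out any of the 4 arrays ended it too (adjusted p from 0.101 to 0.207), with a change of 1.61 to 1.99.

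Of 18 alternative activation markers tested, 9 were called higher and 0 lower over all genes, and 12 and 0 when adjusted over the list alone, with a mean of 3.31 log2 (camera adjusted p = 1.4e-16). With an estimated correlation this list gave adjusted p = 0.013, and fry gave 1.45e-04. Pdcd1lg2, whose product binds an inhibitory receptor on T cells, rose by 6.72 ± 1.00 (adjusted p = 0.012), with 1 of 2 mock arrays above background. Mgl2 rose by 4.43 ± 0.87 (adjusted p = 0.035), Flt1 by 3.70 ± 0.26 (adjusted p = 9.6e-04) and Clec10a by 2.23 ± 0.26 (adjusted p = 0.0053). Among 13 transcription factors of IL-4-primed macrophages, 5 were called higher and 1 lower, and 6 and 2 over the list alone (camera adjusted p = 0.0099, adjusted p = 0.76 with an estimated correlation). These included Batf3 (3.94 ± 0.45, adjusted p = 0.0053) and Egr2 (3.87 ± 0.48, adjusted p = 0.0063), while Cebpb fell by 1.13 ± 0.19 (adjusted p = 0.02). The 14 arginine and polyamine genes had 2 calls higher, over all genes and over the list alone, Arg1 and the arginine transporter gene Slc7a2 (at least 47.8-fold, adjusted p = 2.5e-04), and a mean of 1.41 (camera adjusted p = 0.0249, adjusted p = 0.76 with an estimated correlation). Without C57BL6 mock replicate 1 the transcription factor and the arginine lists each gave adjusted p = 0.0547, and the arginine list had a mean of 0.14 when genes had to be above background on all 12 arrays (adjusted p = 0.604).

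IL-4 receptor signalling had 4 of 13 genes higher and 0 lower, and 4 and 2 over the list alone. Camera, which sets the list against other genes, gave adjusted p = 0.0893, and fry, which tests the list against no change, gave 0.0241. Besides Socs1 and Cish, Socs2 rose by 3.78 ± 0.35 (adjusted p = 0.0022). Inflammatory genes had 1 call higher and 2 lower of 14, and 1 and 4 over the list alone (camera adjusted p = 0.0893). The costimulatory receptor gene Cd40 rose by 2.15 ± 0.28 (adjusted p = 0.0075) and Il18 fell by 0.79 ± 0.16 (adjusted p = 0.037). In Toll-like receptor signalling only Tlr2 was called of 21 genes, lower by -2.69 ± 0.29 (adjusted p = 0.0044), with 2 lower over the list alone (camera adjusted p = 0.151). The 28 interferon response genes had 1 call lower and 3 over the list alone, with a mean of -0.38 (camera adjusted p = 0.0426, adjusted p = 0.84 with an estimated correlation), a call lost with quantile scaling (adjusted p = 0.166) and without C57BL6 mock replicate 1 (0.113), C57BL6 mock replicate 2 (0.0507) or C57BL6 4 h replicate 2 (0.129). Immediate-early genes had 1 call higher and 2 lower of 12, and 2 and 3 over the list alone (camera adjusted p = 0.38): Ier3 rose by 4.13 ± 0.31 (adjusted p = 0.001), and Fos (-2.71 ± 0.36, adjusted p = 0.0079) and Dusp1 (-2.39 ± 0.45, adjusted p = 0.029) fell. Of 23 chemokines 1 was higher and 2 lower, and 2 and 6 over the list alone (camera adjusted p = 0.0893). Among them Ccl8 rose by 3.26 ± 0.49 (adjusted p = 0.013) and Ccl3 fell by 2.32 ± 0.40 (adjusted p = 0.023). No cell cycle gene was called over all genes or over the list alone, although the list mean was -0.65 (camera adjusted p = 0.0019, adjusted p = 0.84 with an estimated correlation).

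In C57BL6 at 4 h 598 of 18427 genes were called, 288 higher and 310 lower, and 258 and 231 of these changed at least 2-fold. At an unadjusted p below 0.05 the count was 2953. Of the called genes 59 were near background on every array of one side. With replicate within strain as a block the count was 3067, and on only the arrays compared it was 71, of which 83.1% were higher instead of 48.2%. Without C57BL6 mock replicate 1 it was 195, without C57BL6 4 h replicate 1 it was 121, without C57BL6 mock replicate 2 it was 186, and without C57BL6 4 h replicate 2 it was 76, the lone sample being assumed to vary like the other groups. Within a slide the median size of the called genes was 1.40 log2 on slide 2 and 1.57 on slide 3, against 1.51 over all arrays. These genes were called from the same arrays, so the agreement was bound to follow and does not test for a slide effect. The call rests on 2 arrays per group, and pairing of the replicates changed its size several-fold.

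**Figure D1:**
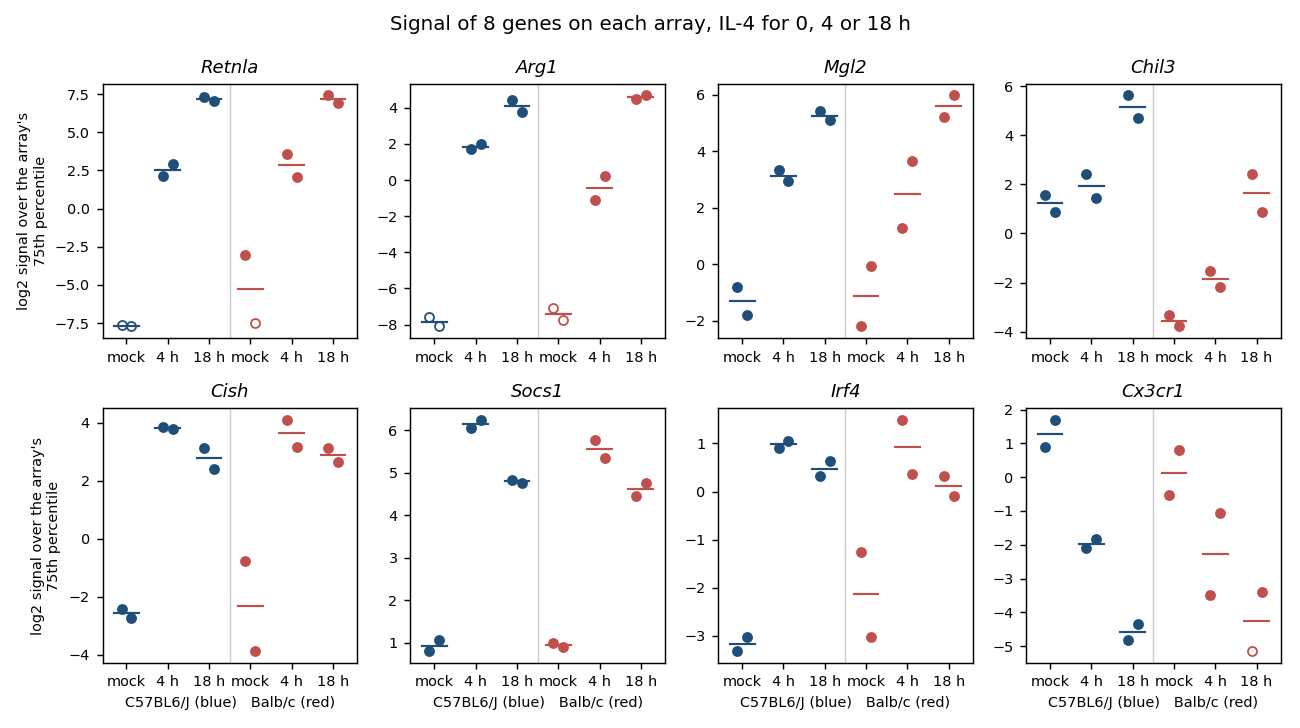
Log2 level relative to the 75th percentile of each array (vertical axis) for 8 genes in mock, 4 h and 18 h of IL-4, with a point per array, open where not well above background, and a line through the mean of 2 arrays per strain. Arg1 rose from near background in both strains to 4.44 and 3.74 in C57BL6 and 4.51 and 4.69 in Balb/c at 18 h.

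What IL-4 had changed by 18 h in C57BL6 macrophages was asked next, again with 2 arrays per group. Retnla and Arg1 rose at least 12152-fold (adjusted p = 9.67e-04) and 1423-fold (adjusted p = 8.05e-05) from near background. Rnase2a, a member of the ribonuclease A family, rose by 8.24 ± 0.43 log2 (302-fold, adjusted p = 1.66e-04), and Mgl2, a galactose-binding lectin of macrophages, by 6.55 ± 0.87 (adjusted p = 0.006). Ccl24, a chemokine that attracts eosinophils, rose by 5.23 ± 1.02 (adjusted p = 0.0285), and Fn1, which encodes fibronectin, by 5.32 ± 0.39 (adjusted p = 8.4e-04). The receptor gene for fractalkine, Cx3cr1, fell by 5.87 ± 0.86 (adjusted p = 0.009). Cxcl10, an interferon-induced chemokine, fell by 4.83 ± 0.57 (28.5-fold, adjusted p = 0.004).

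Tmem26 (6.20 ± 0.29 log2, adjusted p = 1.66e-04), Cish (5.35 ± 0.85, adjusted p = 0.0127), Mcf2l (5.29 ± 0.51, adjusted p = 0.0018) and Cdh1 (5.16 ± 0.54, adjusted p = 0.0027) were the other genes with the largest rises among those above background on every array of both groups. Aqp3, outside that limit with 1 of 2 mock arrays above background and picked after its values were seen, rose by 7.76 ± 0.68 (adjusted p = 0.0013). Falls included Cd300e (-4.49 ± 0.99, adjusted p = 0.046), Itga8 (-4.37 ± 0.69, adjusted p = 0.012), Treml4 (-4.30 ± 0.45, adjusted p = 0.0025), Trim30b (-4.05 ± 0.53, adjusted p = 0.0056), Pilrb1 (-4.01 ± 0.39, adjusted p = 0.0018) and Zmynd15 (-3.90 ± 0.25, adjusted p = 4.02e-04). Nox1, an oxidase subunit, dropped to background, at least 9.66-fold (adjusted p = 0.0319), as did the chemokine gene Cxcl11, at least 7.76-fold (adjusted p = 7.71e-04). Irf4 stayed higher than mock by 3.65 ± 0.56 (adjusted p = 0.0108), with 0.33 and 0.63 on the 18 h arrays, a call that ended when any of the 4 arrays was left out (adjusted p from 0.0624 to 0.0882), while Il4ra was not called (0.02 ± 0.33, adjusted p = 0.989).

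Alternative activation markers had 14 of 18 genes higher and 0 lower, and 16 and 1 over the list alone, with a mean of 4.67 log2 (camera adjusted p = 4.59e-22, adjusted p = 0.0061 with an estimated correlation). The chitinase-like genes Chil3 and Chil4 rose by 3.95 ± 0.59 (adjusted p = 0.0099) and 4.57 ± 0.65 (adjusted p = 0.0081), Flt1 by 5.00 ± 0.26 and the integrin gene Itgax by 3.05 ± 0.39 (adjusted p = 0.0054). Of the primed-macrophage transcription factors 6 were higher and 0 lower, and 7 and 1 over the list alone (mean 1.55, camera adjusted p = 2.62e-05, adjusted p = 0.26 with an estimated correlation). Bhlhe40 rose by 3.59 ± 0.53 (adjusted p = 0.0089) and Klf4 by 2.01 ± 0.32 (adjusted p = 0.012). Among genes of macrophage fusion 3 of 11 were higher, and 4 higher and 2 lower over the list alone (mean 1.02, camera adjusted p = 0.0442, adjusted p = 0.38 with an estimated correlation). They were Ocstamp (4.30 ± 0.33, adjusted p = 8.5e-04), Itgb3 (3.08 ± 0.17, adjusted p = 1.8e-04) and Dcstamp (1.93 ± 0.37, adjusted p = 0.026), and the list gave adjusted p = 0.0635 with the replicate block, 0.0832 without C57BL6 mock replicate 1 and 0.0654 without C57BL6 mock replicate 2.

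The interferon response fell, with 0 of 28 genes higher and 19 lower, and 26 lower over the list alone (mean -1.77, camera adjusted p = 3.65e-25, adjusted p = 0.083 with an estimated correlation, fry 3.17e-04). Ifit3 (-3.65 ± 0.29, adjusted p = 9.4e-04), Ifi44 (-2.74 ± 0.27, adjusted p = 0.0021) and Isg15 (-2.13 ± 0.42, adjusted p = 0.031) were among them. Inflammatory genes had 0 calls higher and 4 lower of 14, and 6 lower over the list alone (mean -1.52, camera adjusted p = 1.72e-04, adjusted p = 0.17 with an estimated correlation), among them Nfkbiz (-2.91 ± 0.39, adjusted p = 0.0061) and Nfkbia (-1.51 ± 0.21, adjusted p = 0.0069). Il1b dropped to background, at least 4.26-fold (adjusted p = 0.03). In Toll-like receptor signalling Tlr2 (-3.19 ± 0.29, adjusted p = 0.0014) and Cd14 (-3.10 ± 0.50, adjusted p = 0.013) were lower, with 6 lower over the list alone (camera adjusted p = 0.0789). Chemokines had 2 calls higher and 7 lower of 23, and 2 and 8 over the list alone (mean -0.82, camera adjusted p = 0.0417, adjusted p = 0.26 with an estimated correlation, 0.0679 with the replicate block, 0.148 without C57BL6 mock replicate 1). With genes above background on all 12 arrays the mean was -0.10 (adjusted p = 0.405). Ccl8 rose by 4.17 ± 0.49 (adjusted p = 0.0039) while Ccl3 (-2.39 ± 0.40, adjusted p = 0.017) and Cxcl16 (-2.31 ± 0.46, adjusted p = 0.032) fell. IL-4 receptor signalling had 3 genes higher and 3 lower over all genes and over the list alone, with a mean of 0.54 and a median of -0.08 (camera adjusted p = 0.797, fry 0.361). Socs1 was still higher by 3.87 ± 0.20 (adjusted p = 1.7e-04), while Il13ra1 fell by 2.33 ± 0.32 (adjusted p = 0.007) and Bcl6 by 0.97 ± 0.21 (adjusted p = 0.045).

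For C57BL6 at 18 h 790 genes were called, 311 higher and 479 lower, of which 268 and 373 changed at least 2-fold, and 3220 had an unadjusted p below 0.05. Near background on every array of one side were 88 of the called genes. The replicate block within strain gave 3209, and the fit on only the arrays compared 321, of which 48.6% were higher instead of 39.4%. Removing C57BL6 mock replicate 1 left 348, C57BL6 18 h replicate 1 206, C57BL6 mock replicate 2 277 and C57BL6 18 h replicate 2 229. On slide 3, where both groups were present, the median size of the called genes was 1.61 log2 against 1.56 over all arrays, for genes called from these same arrays.

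The same question at 4 h in Balb/c macrophages was asked with 2 arrays per group. Cish and Socs1 rose by 5.95 ± 0.85 log2 (adjusted p = 0.0189) and 4.61 ± 0.20 (24.4-fold, adjusted p = 2.17e-04). Arg1 rose at least 36.01-fold (adjusted p = 0.0012), to -1.10 and 0.22. On only the arrays compared no gene was called, and Arg1 had adjusted p = 0.32. Cldn11, a tight junction gene, rose by 4.89 ± 0.45 (adjusted p = 0.004), and Hbegf, a growth factor of the EGF family, by 4.02 ± 0.37 (adjusted p = 0.0043). Nfkbiz (-3.13 ± 0.39, adjusted p = 0.013) and Fos (-2.13 ± 0.36, adjusted p = 0.0354) fell, and so did Clec4e, a receptor for mycobacterial glycolipid (-1.88 ± 0.35, adjusted p = 0.0465). Irf4 rose by 3.06 ± 0.56 (adjusted p = 0.0434), from -1.26 and -3.02 to 1.49 and 0.36, a call that was lost in many settings. It had adjusted p = 0.586 on only the arrays compared, 0.108 with array weights, 0.0892 without the background filter, 0.0598 with a slide block and 0.0531 with median scaling. Without Balb/c 4 h replicate 1 it had adjusted p = 0.184, without Balb/c mock replicate 2 0.118 and without Balb/c 4 h replicate 2 0.0555.

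Further large rises were Wdr86 (5.18 ± 0.67 log2, adjusted p = 0.0144), Tmem26 (4.81 ± 0.29, adjusted p = 0.0012), Rnase2a (4.38 ± 0.43, adjusted p = 0.0055) and Pxdc1 (4.01 ± 0.31, adjusted p = 0.0026). Msx3, Cdh1 and Drd4 rose from near background, at least 99.9-fold (adjusted p = 0.0027), 46.2-fold (adjusted p = 0.0027) and 17.04-fold (adjusted p = 0.0079). Retnla rose by 8.07 ± 1.21 (adjusted p = 0.022), with 1 of 2 mock arrays above background. Jag1 (-2.28 ± 0.37, adjusted p = 0.0283), Mterf2 (-2.25 ± 0.32, adjusted p = 0.0189) and Tlr2 (-2.22 ± 0.29, adjusted p = 0.0147) fell. Jhy, Lrrc17 and Spry3 dropped to background, at least 2.38-fold (adjusted p = 0.0184), 2.38-fold (adjusted p = 0.0175) and 2.34-fold (adjusted p = 0.0147). Il4ra was not called (1.25 ± 0.33, adjusted p = 0.15).

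Alternative activation markers had 7 of 18 genes higher and 0 lower, and 13 and 0 over the list alone (mean 2.99, camera adjusted p = 8.78e-20, adjusted p = 0.008 with an estimated correlation). Flt1 rose by 3.73 ± 0.26 (adjusted p = 0.0015) and Clec10a by 2.03 ± 0.26 (adjusted p = 0.015). Of the primed-macrophage transcription factors 5 were higher and 0 lower, and 5 and 2 over the list alone (mean 1.14, camera adjusted p = 0.0037, adjusted p = 0.53 with an estimated correlation), with Batf3 at 3.81 (adjusted p = 0.011) and Egr2 at 3.08 (adjusted p = 0.026). Without Balb/c 4 h replicate 1 this list gave adjusted p = 0.164. IL-4 receptor signalling had 3 genes higher, and 4 over the list alone, with a mean of 1.03 and a median of -0.08 (camera adjusted p = 0.28, fry 0.0481), and Socs2 rose by 3.87 ± 0.35 (adjusted p = 0.004). The interferon response had 0 genes called and 5 lower over the list alone (mean -0.54, camera adjusted p = 1.19e-05, adjusted p = 0.53 with an estimated correlation). In Toll-like receptor signalling Tlr2 was the only call, with 3 lower over the list alone (mean -0.46, camera adjusted p = 0.0014, adjusted p = 0.32 with an estimated correlation, 0.0598 without Balb/c 4 h replicate 2). Chemokines had 0 genes called and 2 higher and 4 lower over the list alone (mean -0.38, camera adjusted p = 0.0243, adjusted p = 0.32 with an estimated correlation), but the mean was -0.03 without Balb/c 4 h replicate 1 (adjusted p = 0.0804), -0.07 without Balb/c mock replicate 2 (adjusted p = 0.173) and 0.03 with genes above background on all 12 arrays (adjusted p = 0.493). Inflammatory genes had 1 call higher, Cd40 (1.73 ± 0.28, adjusted p = 0.031), and 1 lower, and 1 and 3 over the list alone (camera adjusted p = 0.0622).

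In Balb/c at 4 h 264 genes were called, 174 higher and 90 lower, of which 165 and 71 changed at least 2-fold, and 1864 had an unadjusted p below 0.05. Near background on every array of one side were 48 of the called genes. With the replicate block within strain 1348 genes were called, and the share of called genes that were higher was 46.6% instead of 65.9%. On only the arrays compared 0 genes were called, and array weights gave 50, of which 94% were higher. Without Balb/c mock replicate 1 the count was 67, without Balb/c 4 h replicate 1 it was 113, and without Balb/c mock replicate 2 it was 73. On slide 1 the median size of the called genes was 1.69 log2 against 1.68 over all arrays, for genes called from these same arrays.

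At 18 h the comparison in Balb/c macrophages again had 2 arrays per group. Arg1 rose at least 1185-fold (adjusted p = 7.7e-05) and Retnla by 12.41 ± 1.21 log2 (adjusted p = 0.002), with 1 of 2 mock arrays above background for Retnla. Rnase2a rose by 9.62 ± 0.43 (785-fold, adjusted p = 1.28e-04), Cldn11 by 7.33 ± 0.45 (adjusted p = 2.57e-04) and the lectin gene Mgl2 by 6.74 ± 0.87 (adjusted p = 0.0052). Chil3, a chitinase-like protein secreted by alternatively activated macrophages, rose by 5.20 ± 0.59 (36.8-fold, adjusted p = 0.0033). The antiviral genes Ifit3 (-4.62 ± 0.29, adjusted p = 2.9e-04), Ifit2 (-4.20 ± 0.22, adjusted p = 1.86e-04) and Ifit1 (-3.82 ± 0.31, adjusted p = 0.001) fell. Cxcl10 fell by 5.38 ± 0.57 (41.6-fold, adjusted p = 0.0026), and Rsad2, which encodes an antiviral radical enzyme, fell by 3.69 ± 0.49 (adjusted p = 0.0061).

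Tmem26 (5.78 ± 0.29 log2, adjusted p = 1.57e-04), Cish (5.21 ± 0.85, adjusted p = 0.0143), Pdlim1 (5.14 ± 0.36, adjusted p = 6.25e-04) and Flt1 (5.09 ± 0.26, adjusted p = 1.57e-04) rose too. Msx3, Cdh1 and Tarm1 rose from near background, at least 171.4-fold (adjusted p = 7.08e-04), 53.5-fold (adjusted p = 0.001) and 19.6-fold (adjusted p = 2.25e-04). Pilrb1 (-3.95 ± 0.39, adjusted p = 0.002), Itga8 (-3.75 ± 0.69, adjusted p = 0.0227) and Pilra (-3.51 ± 0.58, adjusted p = 0.0148) fell. Fpr2, a receptor for formylated peptides, dropped to background, at least 18.3-fold (adjusted p = 9.12e-04), and so did Cxcl11 (at least 12.96-fold, adjusted p = 2.9e-04) and Slfn1 (at least 8.02-fold, adjusted p = 0.0019). Irf4 was not called (2.26 ± 0.56, adjusted p = 0.0758), with -1.26 and -3.02 on the mock arrays. It was called with the replicate block (adjusted p = 0.0082), with a mean-variance trend (adjusted p = 0.0449) and with the local background offset (adjusted p = 0.0368). Without Balb/c mock replicate 1 its change was 3.14. Il4ra was not called (-0.11, adjusted p = 0.918).

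Alternative activation markers had 12 of 18 genes higher and 0 lower, and 14 and 0 over the list alone (mean 4.60, camera adjusted p = 6.53e-22, adjusted p = 0.0062 with an estimated correlation). Chil4 rose at least 14.7-fold (adjusted p = 0.0045) and Itgax by 1.93 ± 0.39 (adjusted p = 0.036). The interferon response had 0 of 28 genes higher and 25 lower, and all 28 lower over the list alone (mean -2.35, camera adjusted p = 2.74e-38, adjusted p = 0.03 with an estimated correlation). Mx2 was lower by -3.07, Iigp1 by -3.06, Mx1 by -2.85 and Isg15 by -2.83 ± 0.42 (adjusted p = 0.0098). Inflammatory genes had 0 calls higher and 5 lower, and 1 and 5 over the list alone (mean -1.23, camera adjusted p = 2.69e-05, adjusted p = 0.12 with an estimated correlation), among them Il1b (-3.13 ± 0.51, adjusted p = 0.014), Il18 (-1.32 ± 0.16, adjusted p = 0.0038) and Icam1 (-1.002 ± 0.22, adjusted p = 0.048). In Toll-like receptor signalling 4 genes were lower, and 8 over the list alone (mean -0.65, camera adjusted p = 1.16e-04, adjusted p = 0.16 with an estimated correlation), with Tlr2 at -3.17 (adjusted p = 0.0016) and the adaptor gene Myd88 at -0.67 ± 0.14 (adjusted p = 0.043).

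Chemokines had 1 call higher and 7 lower over all genes and over the list alone (mean -0.64, camera adjusted p = 0.0329, adjusted p = 0.22 with an estimated correlation, 0.0764 with the replicate block, 0.174 without Balb/c mock replicate 2). With genes above background on all 12 arrays the mean was -0.04 (adjusted p = 0.307). Ccl8 rose by 4.47 ± 0.49 (adjusted p = 0.0029), and Cx3cr1 fell by 4.41 ± 0.86 (adjusted p = 0.031), with 1 of 2 IL-4 arrays above background. Of the transcription factors of primed macrophages 5 were higher, and 6 over the list alone (mean 1.18, camera adjusted p = 3.26e-04, adjusted p = 0.33 with an estimated correlation), with Klf4 at 2.75 (adjusted p = 0.0034) and Batf3 at 2.93 (adjusted p = 0.011). Arginine and polyamine genes had 2 calls higher over all genes and over the list alone (mean 1.43, camera adjusted p = 0.007, adjusted p = 0.33 with an estimated correlation, 0.112 without Balb/c mock replicate 1), with a mean of 0.22 over genes above background on all 12 arrays (adjusted p = 0.508), and Slc7a2 rose by 4.07 ± 0.35 (adjusted p = 0.0013). Fusion genes had 2 higher over all genes and over the list alone (camera adjusted p = 0.148), Itgb3 at 3.60 (adjusted p = 1.3e-04) and Ocstamp at 2.31 ± 0.33 (adjusted p = 0.0079). IL-4 receptor signalling had 3 genes higher and 2 lower, and 3 and 5 over the list alone, with a mean of 0.42, a median of -0.11 and a camera direction of down (adjusted p = 0.787, fry 0.698). Il13ra1 fell by 2.57 ± 0.32 (adjusted p = 0.0046) and the phosphatase gene Ptpn6 by 0.77 ± 0.15 (adjusted p = 0.029).

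Balb/c at 18 h gave 687 called genes, 252 higher and 435 lower, of which 223 and 373 changed at least 2-fold, and 2788 had an unadjusted p below 0.05. Near background on every array of one side were 127 of the called genes. The replicate block within strain gave 2786. On only the arrays compared the count was 17, and 70.6% of these were higher instead of 36.7%. Leaving out Balb/c mock replicate 1 gave 353, Balb/c 18 h replicate 1 323, Balb/c mock replicate 2 446 and Balb/c 18 h replicate 2 314. On slide 1 the median size of the called genes was 1.67 log2 against 1.66 over all arrays, for genes called from these same arrays. Over all comparisons, the list calls that held with an estimated correlation were the alternative activation markers in each of the 4 IL-4 comparisons with mock and the interferon response in Balb/c at 18 h, 5 of the 57 calls, and 28 of them held with fry.

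**Figure D2:**
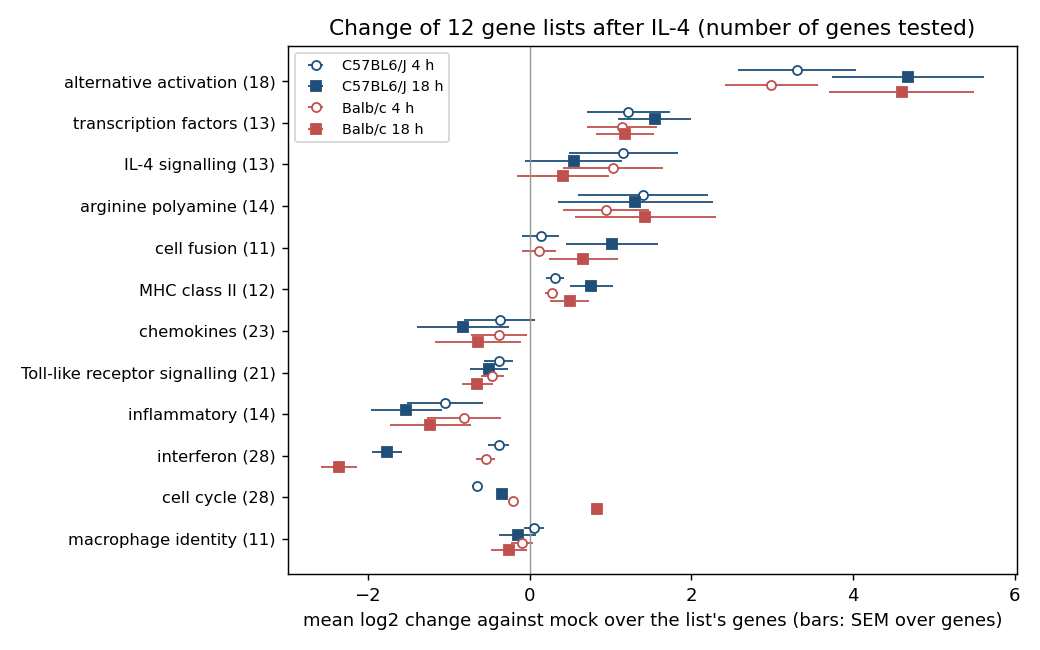
Mean log2 change over the genes of 12 lists (horizontal axis) after 4 h and 18 h of IL-4 against mock in each strain, with bars for the standard error over genes. Alternative activation markers lay at 4.67 and 4.60 at 18 h, and the interferon response at -1.77 and -2.35. The marker means include genes near background in mock, such as Arg1, and are not exact sizes.

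Whether the strains changed the same genes was asked from the overlap of the calls, for which the strains share no array. At 4 h 219 genes were called in the same direction in both strains, 148 higher (2.72 for independent lists) and 71 lower (1.51), and 0 in opposite directions. Socs1, Cish, Tmem26 and Rnase2a were among the shared rises and Nfkbiz, Jag1 and Tlr2 among the shared falls. At 18 h the overlap was 455, 178 higher (4.25 for independent lists) and 277 lower (11.3), and 1 gene had opposite signs. Arg1, Mgl2, Chil3 and Flt1 rose in both strains by 18 h, and Cxcl10, Ifit3, Pilrb1 and Itga8 fell in both. Log2 changes of all genes correlated between strains at 0.63 at 4 h and 0.605 at 18 h. Of genes called in C57BL6, 97.3% at 4 h and 96.1% at 18 h had the same sign in Balb/c, and the reverse shares were 98.5% and 96.9%. Genes called higher in C57BL6 at 4 h had a median of 1.86 log2 there and 1.33 in Balb/c, while those called higher in Balb/c had 1.94 there and 1.90 in C57BL6.

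**Figure D3:**
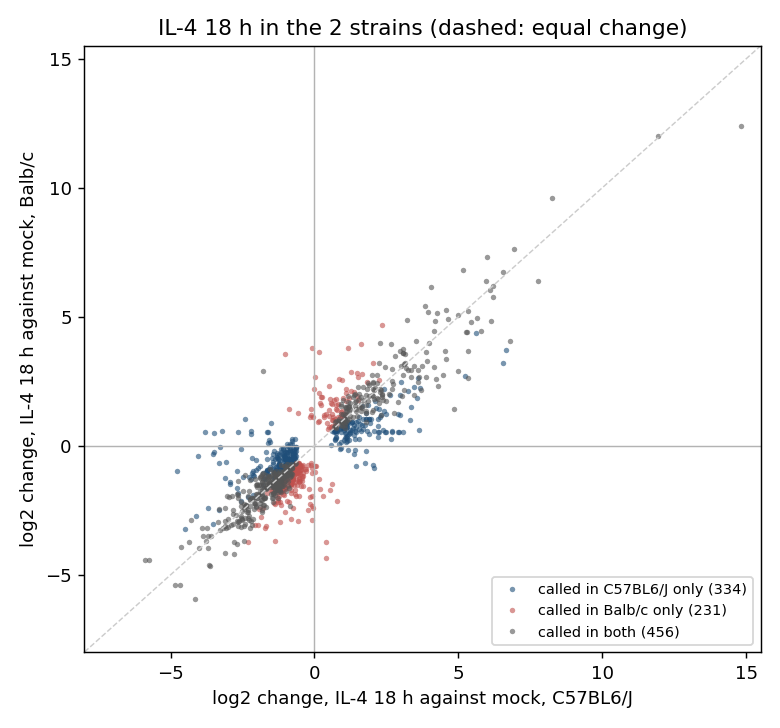
Log2 change after 18 h of IL-4 in C57BL6 (horizontal axis) against Balb/c (vertical axis), with a point per gene coloured by the strain in which it was called. Of the genes shown, 456 were called in both strains, 334 in C57BL6 alone and 231 in Balb/c alone. The points lay along the diagonal. The correlation was 0.605 over all tested genes, most of which are not shown, and 0.92 over the genes called in C57BL6.

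Within a strain, C57BL6 had 302 genes called in the same direction at 4 h and 18 h, 155 higher (4.86 for independent lists) and 147 lower (8.06), and 1 with opposite signs. Balb/c had 177, 120 higher (2.38) and 57 lower (2.12), and 0 with opposite signs. Socs1, Cish, Batf3, Egr2 and Itgb3 rose at both times in both strains, and Nfkbiz and Tlr2 fell at both. Both times shared the mock arrays, which the counts for independent lists do not allow for. In 20 simulations without any change there were 0 shared calls, as had to follow when no gene changes, so this sets no baseline for the overlap. The simulated correlation was 0.50 in each strain, against 0.67 in C57BL6 and 0.675 in Balb/c. The covariance was 0.32 in C57BL6 and 0.282 in Balb/c, against 0.0894 and 0.0899 in the simulations. The simulations left out the pairing of the replicates, so these values are not an exact baseline.

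Which genes changed between 4 h and 18 h of IL-4 was tested over both strains, with 4 arrays at each time. Incubation time changed together with the length of IL-4, and mock cells were kept for 18 h only. The effects of IL-4 length and of incubation time cannot be told apart here. Late genes included Rnase2a (5.13 ± 0.30 log2, adjusted p = 7.49e-04), Retnla (4.50 ± 0.86, adjusted p = 0.0292) and Arg1 (3.64 ± 0.32, 12.5-fold, adjusted p = 0.0014). Fn1, a matrix protein gene, rose further by 3.37 ± 0.28 (adjusted p = 0.0011), and the chitinase-like genes Chil3 and Chil4 by 3.37 ± 0.42 (adjusted p = 0.0051) and 3.19 ± 0.46 (adjusted p = 0.01). Serpina3g was lower at 18 h (-3.35 ± 0.26, adjusted p = 9.18e-04), and so was Il4ra (-1.57 ± 0.23, adjusted p = 0.0109), a call lost without C57BL6 4 h replicate 2 (adjusted p = 0.0545) or C57BL6 18 h replicate 2 (adjusted p = 0.051). Gata3, a transcription factor of type 2 lymphocytes, dropped to background by 18 h, at least 12.8-fold (adjusted p = 9.65e-04), and Kalrn at least 8.76-fold (adjusted p = 0.0017). Gbp4, which encodes a guanylate-binding protein (-2.92 ± 0.35, adjusted p = 0.0044), Isg20 (-2.89 ± 0.33, adjusted p = 0.0036), Plac8 (-2.75 ± 0.54, adjusted p = 0.0334) and Ifit2 (-2.73 ± 0.16, adjusted p = 7.49e-04) fell. Gfra2 rose from background, at least 5.96-fold (adjusted p = 0.0079), and Irf4 was not called (-0.65 ± 0.39, adjusted p = 0.483).

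The interferon response fell between the times, with 0 of 28 genes higher and 22 lower, and all 28 lower over the list alone (mean -1.60, camera adjusted p = 2.44e-35, adjusted p = 0.06 with an estimated correlation). Ifit3 fell by 2.83 ± 0.20 (adjusted p = 8.76e-04). Alternative activation markers had 8 genes higher and 0 lower, and 9 and 1 over the list alone (mean 1.49, camera adjusted p = 1.93e-07, adjusted p = 0.06 with an estimated correlation), with Itgax at 1.91 ± 0.28 (adjusted p = 0.0099), Flt1 at 1.33 ± 0.18 (adjusted p = 0.0077) and Mrc1 at 0.60 ± 0.13 (adjusted p = 0.049). IL-4 receptor signalling had 0 higher and 5 lower, and 7 lower over the list alone (mean -0.61, camera adjusted p = 1.34e-04, adjusted p = 0.37 with an estimated correlation), with Socs2 at -1.53 ± 0.25 (adjusted p = 0.016), Il13ra1 at -1.49 ± 0.23 (adjusted p = 0.013) and Socs1 at -1.15 ± 0.14 (adjusted p = 0.0047). Inflammatory genes had 0 higher and 5 lower, and 6 lower over the list alone (mean -0.45, camera adjusted p = 0.0018, adjusted p = 0.27 with an estimated correlation), with Cd40 at -1.45 ± 0.20 (adjusted p = 0.0079) and Cd86 at -1.42 ± 0.27 (adjusted p = 0.029). Fusion genes had 3 higher and 0 lower, and 4 and 1 over the list alone (mean 0.72, camera adjusted p = 0.0112, adjusted p = 0.27 with an estimated correlation, 0.0536 without the background filter), with Ocstamp at 2.84 and Dcstamp at 1.69. Immediate-early genes had 1 call, Fos (1.83 ± 0.26, adjusted p = 0.0084), and 2 over the list alone (mean 0.43, camera adjusted p = 0.016, adjusted p = 0.27 with an estimated correlation, 0.0569 without C57BL6 4 h replicate 1).

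Between the times 687 genes were called, 259 higher and 428 lower at 18 h, of which 127 and 249 changed at least 2-fold, and 3073 had an unadjusted p below 0.05. Near background on every array of one side were 36 of the called genes. With the replicate block within strain the count was 3109, of which 49.3% were higher instead of 37.7%, and on only the arrays compared it was 432. Without Balb/c 18 h replicate 1 it was 318, without Balb/c 18 h replicate 2 it was 445, without C57BL6 4 h replicate 1 it was 266, without C57BL6 18 h replicate 1 it was 281, without C57BL6 4 h replicate 2 it was 275 and without C57BL6 18 h replicate 2 it was 267.

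How untreated Balb/c macrophages differed from untreated C57BL6 macrophages was asked with 2 arrays per strain. Ifi202b, an interferon-inducible gene that C57BL6 mice are known to express little of, was near background in C57BL6 and at least 4874-fold higher in Balb/c (adjusted p = 4.11e-06). H2-Ea, the class II gene that the C57BL6 haplotype does not express, was at least 169.9-fold higher (adjusted p = 2.83e-04), with 0.31 to 1.73 on the 6 Balb/c arrays. Nnt, a mitochondrial enzyme partly deleted in C57BL6/J mice, was higher in Balb/c by 1.202 ± 0.22 log2 (adjusted p = 0.0195). Chil3, secreted by alternatively activated macrophages, was lower in Balb/c by -4.78 ± 0.59 (27.5-fold, adjusted p = 0.0032). Il1b, the gene of a fever-inducing cytokine, was higher by 3.42 ± 0.51 (adjusted p = 0.0073).

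Atp6v0e2 (7.44 ± 0.34 log2, adjusted p = 2.61e-05), Msh5 (5.79 ± 0.21, adjusted p = 1.14e-05), Cpne8 (5.39 ± 0.65, adjusted p = 0.0028), Jaml (5.18 ± 1.13, adjusted p = 0.0394), Chst10 (5.11 ± 0.19, adjusted p = 1.14e-05) and Nrcam (4.74 ± 0.24, adjusted p = 3.87e-05) were higher in Balb/c. Gbp2b was at least 271.03-fold higher (adjusted p = 4.79e-05). Uchl1 (-5.59 ± 0.48, adjusted p = 5.18e-04), Padi4 (-5.25 ± 0.31, adjusted p = 8.28e-05), Spint1 (-4.92 ± 0.84, adjusted p = 0.0142), C5ar2 (-4.50 ± 0.31, adjusted p = 1.9e-04) and Prim2 (-4.31 ± 0.35, adjusted p = 4.29e-04) were lower. Trim12a and Thumpd1 were at background in Balb/c, at least 684-fold (adjusted p = 2.18e-06) and 235-fold lower (adjusted p = 1.14e-05). Irf4 (1.04 ± 0.56, adjusted p = 0.346) and Il4ra (0.03, adjusted p = 0.975) were not called, and Arg1 was near background in both strains (0.45, adjusted p = 0.626).

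Neutrophil markers had 0 of 8 genes higher and 5 lower in Balb/c, and 6 lower over the list alone (mean -1.62, camera adjusted p = 3.9e-05, adjusted p = 0.89 with an estimated correlation, fry 0.0133). They were Camp (-2.85 ± 0.32, adjusted p = 0.002, 1 of 2 Balb/c arrays above background), Ngp (-2.04 ± 0.24, adjusted p = 0.0025), Ltf (-1.89 ± 0.24, adjusted p = 0.0037), S100a9 (-1.82 ± 0.29, adjusted p = 0.01) and S100a8 (-1.81 ± 0.29, adjusted p = 0.0095). Dendritic cell markers had 1 of 6 higher and 3 over the list alone (mean 1.52, camera adjusted p = 0.0192, adjusted p = 0.89 with an estimated correlation), with Cd209a at least 5.11-fold higher (adjusted p = 0.0093). That list call was lost without Balb/c mock replicate 1 (adjusted p = 0.135) or C57BL6 mock replicate 2 (adjusted p = 0.214) and with slide as a term (adjusted p = 0.127). Cell cycle genes had 0 called over all genes and over the list alone, with a mean of -0.855 (camera adjusted p = 0.0017, adjusted p = 0.96 with an estimated correlation), and cholesterol synthesis likewise 0 with a mean of -0.67 (camera adjusted p = 0.0169, adjusted p = 0.96 with an estimated correlation). Without Balb/c mock replicate 1 these means were -0.15 (adjusted p = 0.837) and -0.33 (adjusted p = 0.559), and with slide as a term -0.11 (adjusted p = 0.693) and -0.49 (adjusted p = 0.122). Without C57BL6 mock replicate 2 cholesterol synthesis gave -0.42 (adjusted p = 0.373). Toll-like receptor signalling had 0 called by either count (mean 0.22, camera adjusted p = 0.0426, adjusted p = 0.95 with an estimated correlation), a call lost without Balb/c mock replicate 1 (adjusted p = 0.344) and without either C57BL6 mock array (adjusted p = 0.109 and 0.139). The interferon response had 1 call by either count, Ifi44 (2.97 log2), and alternative activation markers had 0 higher and 3 lower, and 1 and 4 over the list alone, with a mean of -0.28 and a median of 0.13 (camera adjusted p = 0.913 for each). Flt1 was lower by -1.72 ± 0.26 (adjusted p = 0.0075). Arginine and polyamine genes had 2 higher and 3 over the list alone, with a mean of 0.29 and a median of -0.31 (camera adjusted p = 0.913), and Slc7a2 and Arg2 were at least 3.386-fold (adjusted p = 0.0029) and 16.5-fold higher (adjusted p = 0.0062). Both genes of the strain check list, H2-Ea and Nnt, were higher.

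Between the untreated strains 966 genes were called, 459 higher and 507 lower in Balb/c, of which 378 and 399 differed at least 2-fold, and 3618 had an unadjusted p below 0.05. Near background on every array of one side were 193 of the called genes. Without Balb/c mock replicate 1 the count was 449, without C57BL6 mock replicate 1 it was 498, and without C57BL6 mock replicate 2 it was 538. Mock arrays of the strains never shared a slide, and with slide as a term 505 genes were called. On only the arrays compared the count was 249.

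Whether IL-4 changed a gene by a different amount in the strains was tested as the difference of the effects, with 2 arrays in each of the 4 groups compared at each time. Arg1 was near background on every mock array, so its Balb/c effect minus its C57BL6 effect (-2.73 log2 at 4 h, adjusted p = 1, and 0.07 at 18 h, adjusted p = 0.997) rests on levels that were not measured. For Irf4 the difference was -1.09 ± 0.79 (adjusted p = 1) and -1.39 ± 0.79 (adjusted p = 0.931). Il4ra (-0.55 and -0.12) and Nnt (0.25 and 0.22) were not called either, nor was H2-Ea (0.17 and 0.47), which was near background on every C57BL6 array, so that these sizes are not well measured. With limma 0 genes were called at each time, while 447 at 4 h and 977 at 18 h had an unadjusted p below 0.05. For a planted 2-fold difference of this kind the self-test recovered 4% of genes at 4 h and 2% at 18 h. A 4-fold difference was recovered in 54% at each time, so moderate strain differences could go uncalled. Alternatives gave 2 with quantile scaling and 1 with the deposited ratios at 4 h, and 2 with median scaling, 9 with quantile scaling, 1 with the deposited ratios, 1 with the background offset and 2 with a slide block at 18 h. The replicate block within strain gave 0 at both times. Without Balb/c 4 h replicate 1 or replicate 2 the 4 h count was 4, and without Balb/c mock replicate 1 the counts were 1 at 4 h and 4 at 18 h. Without Balb/c mock replicate 2 the 18 h count was 1.

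As lists, the interferon response fell more in Balb/c at 18 h, by a mean of -0.59 (camera adjusted p = 1.34e-07, adjusted p = 0.88 with an estimated correlation) with 0 of 28 genes called over all genes and over the list alone. Its largest member difference was that of Ifit2 (-1.42 ± 0.31, adjusted p = 0.57). Cell cycle genes differed by 1.17 at 18 h (camera adjusted p = 3.28e-11, adjusted p = 0.88 with an estimated correlation), with 0 called, and by 0.46 without Balb/c mock replicate 1. At 4 h their difference was 0.44 (camera adjusted p = 0.0183, adjusted p = 0.86 with an estimated correlation), but it was 0.07 with a slide block (adjusted p = 0.839) and its direction hung on single arrays: it was -0.27 without Balb/c mock replicate 1, -0.09 without Balb/c 4 h replicate 2 and 1.15 without Balb/c mock replicate 2. Stromal markers differed by 0.77 at 4 h (camera adjusted p = 0.0038, adjusted p = 0.86 with an estimated correlation) and 0.90 at 18 h (camera adjusted p = 0.0013, adjusted p = 0.88 with an estimated correlation), with 0 called and 3 higher over the list alone at 18 h. Without C57BL6 mock replicate 1 these were 0.45 (adjusted p = 0.148) and 0.59 (adjusted p = 0.0529), and the 4 h call was also lost without Balb/c 4 h replicate 1 (adjusted p = 0.0593) or Balb/c mock replicate 2 (adjusted p = 0.146). Arginine and polyamine genes differed by -0.47 at 4 h (camera adjusted p = 0.037, adjusted p = 0.86 with an estimated correlation, and 0.165 with the replicate block), with 0 called and 2 lower over the list alone, and the mean was -0.20 without Balb/c 4 h replicate 1 (adjusted p = 0.48). With genes above background on all 12 arrays it was 0.02 (adjusted p = 0.779), and the deposited ratios gave -0.42 (adjusted p = 0.0832). Alternative activation markers were not called as a list (camera adjusted p = 0.362 at 4 h and 0.991 at 18 h).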

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

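The values in this part drew attention because a strain or a time differed in the effect of IL-4 or a sign changed, and the tests of the cell cycle shift by slide and by array were written only after the result had been seen, with the rules of the array test and of the splits tightened later in the cautious direction.

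The strains differed in how far some gene lists moved with IL-4 although no gene was called for such a difference. At 4 h these were cell cycle genes (0.44 log2, Balb/c effect minus C57BL6 effect), arginine and polyamine genes (-0.47) and stromal markers (0.77). The cell cycle value was -0.27 without Balb/c mock replicate 1, -0.09 without Balb/c 4 h replicate 2 and 0.07 with a slide block. The arginine value was -0.20 without Balb/c 4 h replicate 1 and 0.02 with genes above background on all 12 arrays. Stromal markers gave 0.45 without C57BL6 mock replicate 1. At 18 h the lists were the interferon response (-0.59), cell cycle genes (1.17) and stromal markers (0.90, but 0.59 without C57BL6 mock replicate 1). No such list call held with an estimated correlation.

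The cell cycle shift at 18 h drew attention because it pointed up in Balb/c and not in C57BL6. The list means of the Balb/c arrays on slide 1 ranged over 1.47 log2 within that slide. Those arrays differed in treatment too, so the range does not test for a slide effect. Compared within a slide, 18 h against mock had a list median of 0.61 in Balb/c on slide 1 (1 against 2 arrays). In C57BL6 on slide 3 it was -0.38 (2 against 1 arrays), so the opposite directions were also seen within slides. Balb/c mock replicate 1 lay at -1.56 and Balb/c mock replicate 2 at -0.15, relative to the C57BL6 mock mean, and without replicate 1 the shift was 0.46 (camera adjusted p = 1.31e-04) instead of 1.17. Balb/c 4 h replicate 1 lay as low (-1.61) but Balb/c 18 h replicate 1 did not (-0.23), and within replicates 18 h minus mock was 1.34 and 0.32 in Balb/c against -0.47 and -0.22 in C57BL6. Whether the shift rests on that culture cannot be told, and a strain difference in how IL-4 acts on the cell cycle stays open, as it was not tested beyond these arrays.

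The 687 genes called between 4 h and 18 h of IL-4 drew attention as a change over time in a design where replicate and slide vary as well. Every split of the 8 IL-4 arrays into sets of 4 was fitted with strain as a term. Of 34 splits that could be fitted, 1 called as many genes as the real times, namely the real split itself with 669, and the highest other split called 35. The replicates were paired, however, and only 8 splits parted all pairs as the real one does, with 0 as the highest other value, which is too few splits for a share under 0.05.

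Opposite signs drew attention in a pair of genes, chosen after the values were seen. The transcript AW476689 was called higher in Balb/c at 18 h (2.91 ± 0.37 log2, adjusted p = 0.0048) and lower in C57BL6 (-1.80 ± 0.37, adjusted p = 0.035), yet the difference was not called (adjusted p = 0.156). It lay near background, with 0 of 2 mock arrays and 1 of 2 arrays at 18 h above it in Balb/c, so these sizes are not well measured. Fzd1, a Wnt receptor gene, dropped to background in C57BL6 at 4 h (at least 4.26-fold, adjusted p = 0.0358) and was higher at 18 h (2.20, adjusted p = 0.0446).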

How the results depend on the processing

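Every alternative except the array quality weights and the local background offset was chosen before the data were examined. Unless stated, the cause of a change was not tested.

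Normexp background correction brought the counts to 24 in C57BL6 at 4 h, 129 in C57BL6 at 18 h, 3 in Balb/c at 4 h, 138 in Balb/c at 18 h, 131 between the times and 30 between the untreated strains. Overlaps were 3 between strains at 4 h, 87 at 18 h, 16 between times in C57BL6 and 3 in Balb/c. It also reversed values: Ccr1 (-1.34) and Gfra2 (-0.45) between the times, Cd209a (-0.34) and Slc7a2 (-0.50) between the untreated strains, and Jhy (0.22), Lrrc17 (0.36) and Spry3 (0.40) in Balb/c at 4 h. Reversed lists were the dendritic markers between the untreated strains (-0.33), the interferon response in C57BL6 at 4 h (-0.20, by camera direction) and the cell cycle in the strain difference at 4 h (0.25, by camera direction). Its fitted background mean ran from 0.15 down to -958, while negative controls averaged 4.8 to 57.8, so the fit of the background had failed on several arrays. The simple background offset, chosen after that, called 1 gene for the strain difference at 18 h, and gave 826 and 1004 in C57BL6, 312 and 774 in Balb/c, 882 between the times, 1113 between the strains and an overlap between times of 402 in C57BL6.

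Without the background filter the counts were 304 and 463 in C57BL6 at 4 h and 18 h, 120 and 437 in Balb/c, 360 between the times and 590 between the strains. Overlaps were 99 between strains at 4 h, 279 at 18 h, 157 between times in C57BL6 and 82 in Balb/c. A fit on only the arrays compared gave 71, 321, 0, 17, 432 and 249 in the same order, having fewer arrays to estimate the spread.

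The replicate block within strain gave 3067 and 3209 in C57BL6, 1348 and 2786 in Balb/c and 3109 between the times. Its overlaps were 1097 between strains at 4 h, 1581 at 18 h, 1590 between times in C57BL6 and 860 in Balb/c. Among genes and list members followed, 480 entries were unchanged, which includes genes called in neither fit, 48 calls were gained and none was lost. Of the lists 47 were unchanged and 5 were lost, namely the chemokines in both strains, the fusion genes in C57BL6 and glycolysis in Balb/c at 18 h (adjusted p = 0.0516), and the arginine and polyamine genes in the strain difference at 4 h. The block changed no other list call. The block across strains gave 1097, 1410, 406, 1102, 1265 and 1726, with overlaps of 343 between strains at 4 h, 733 at 18 h, 565 between times in C57BL6 and 281 in Balb/c.

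Median scaling gave 376 in C57BL6 at 4 h and 420 between the times, an overlap between times of 194 in C57BL6, and 2 genes for the strain difference at 18 h. Quantile scaling called 2 genes for the strain difference at 4 h and 9 at 18 h, the deposited ratios 1 and 1, and a slide block 2 at 18 h and 505 between the untreated strains. Array quality weights gave 987 and 1283 in C57BL6 and 50 in Balb/c at 4 h, where the weights of the Balb/c 4 h arrays were 0.546.

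Leaving out an array gave 76 to 195 in C57BL6 at 4 h, 206 to 348 in C57BL6 at 18 h, 67 to 194 in Balb/c at 4 h, 314 to 446 in Balb/c at 18 h, 266 to 538 between the times and 449 to 749 between the untreated strains. For the strain differences it gave 0 to 4 at each time. The cell cycle list in the strain difference at 4 h was reversed without Balb/c mock replicate 1 (-0.27) and without Balb/c 4 h replicate 2 (-0.09), and was 1.15 without Balb/c mock replicate 2. Among the genes followed, 2471 entries were unchanged, called or not, 566 calls were lost and 3 were gained.

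Gene entries left unchanged in other settings, called or not, were 562 with median scaling, 590 with quantile scaling, 590 with the deposited ratios, 526 without the filter, 594 with a trend and 568 with a slide block. On only the arrays compared 182 gene calls were lost, and normexp left 343 gene entries unchanged. List calls lost were 12 with a slide block, 12 with the filter on all 12 arrays, 7 with the background offset, 5 with quantile scaling and 55 over the arrays left out. Of the list calls 5 held and 52 were lost with an estimated correlation. Signal near background limits the folds of genes absent from one group, which stay bounds.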

Other observations

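The tests of the share of higher genes and of the slide term for the strain calls were chosen only after the result was seen, while those of further probes, neighbours and granulocyte genes were written before, with the rule for further probes tightened afterwards in the cautious direction.

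No gene of the lists of energy and lipid metabolism was called in any comparison over all genes. Oxidative phosphorylation had 0 of 21 genes called in either strain at 18 h, and 2 higher over the list alone in C57BL6 and 0 in Balb/c, with a mean of 0.16 in C57BL6 (camera adjusted p = 0.0216, adjusted p = 0.75 with an estimated correlation, and 0.0857 without C57BL6 18 h replicate 1) and 0.30 in Balb/c (camera adjusted p = 5.68e-05, adjusted p = 0.44 with an estimated correlation). Cholesterol synthesis had 0 of 21 called and a mean of 0.60 in Balb/c at 18 h (camera adjusted p = 7.92e-05, adjusted p = 0.64 with an estimated correlation), and glycolysis 0 of 17 and a mean of 0.25 (camera adjusted p = 0.0489, adjusted p = 0.68 with an estimated correlation). Both rested on replicate 1, where 18 h minus mock was 1.18 and 0.48, against 0.01 and 0.02 in replicate 2, and without Balb/c mock replicate 1 the means were 0.26 (adjusted p = 0.112) and 0.05 (adjusted p = 0.796). Fatty acid oxidation lay below mock at 4 h (mean -0.23 in C57BL6 and -0.13 in Balb/c) and near it at 18 h (0.09 and 0.05), with 0 of 16 called between the times and 3 higher over the list alone (mean 0.25, camera adjusted p = 0.0112, adjusted p = 0.62 with an estimated correlation), and the call was lost without Balb/c 18 h replicate 1 (adjusted p = 0.158) or Balb/c 4 h replicate 2 (adjusted p = 0.131). Ribosomal proteins had 0 of 23 called and a mean of 0.20 in C57BL6 (camera adjusted p = 0.0098, adjusted p = 0.75 with an estimated correlation, but 0.783 without C57BL6 mock replicate 2) and 0.22 in Balb/c at 18 h (camera adjusted p = 0.0028, adjusted p = 0.75 with an estimated correlation). Cell cycle genes had 0 of 28 called and a mean of 0.83 in Balb/c at 18 h (camera adjusted p = 6.2e-07, adjusted p = 0.62 with an estimated correlation), which was 0.12 without Balb/c mock replicate 1 (adjusted p = 0.234). The cholesterol, glycolysis, ribosomal, cell cycle and class II lists had 0 called over the list alone as well. MHC class II had 0 of 12 called, with a mean of 0.76 in C57BL6 at 18 h (camera adjusted p = 0.0353, adjusted p = 0.75 with an estimated correlation, and 0.0832 without C57BL6 mock replicate 1), and lysosome genes had 0 of 20 called in any comparison, with the smallest camera adjusted p at 0.0651. Between 4 h and 18 h of IL-4 camera placed higher the cell cycle (mean 0.67, adjusted p = 1.56e-07), cholesterol synthesis (0.48, adjusted p = 9.61e-06), oxidative phosphorylation (0.21, adjusted p = 3.3e-05), glycolysis (0.17, adjusted p = 0.0244) and ribosomal proteins (0.15, adjusted p = 0.003), with 0 genes called and none holding with an estimated correlation (smallest adjusted p = 0.48). Of these, glycolysis was lost without Balb/c 4 h replicate 1 (adjusted p = 0.241) and ribosomal proteins without Balb/c 4 h replicate 2 (adjusted p = 0.0926).

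Markers of other cells and of the macrophage itself gave few calls. Fcgr1, the high-affinity receptor for IgG, was the only called gene of 11 macrophage identity genes and fell by 1.97 ± 0.24 log2 in C57BL6 (adjusted p = 0.0047) and 1.90 ± 0.24 in Balb/c at 18 h (adjusted p = 0.005), with the smallest camera adjusted p of that list at 0.219. Ear1, an eosinophil-associated ribonuclease in a list of 3 genes too small to test, rose by 5.65 ± 0.56 in C57BL6 (adjusted p = 0.0021, 1 of 2 mock arrays above background) and at least 13.7-fold in Balb/c at 18 h (adjusted p = 0.0032). The platelet chemokine gene Ppbp, of 5 megakaryocyte markers, fell by 1.63 ± 0.35 in C57BL6 at 18 h (adjusted p = 0.043), with the smallest camera adjusted p of that list at 0.474. Neutrophil markers had 0 higher and 1 lower of 8 in Balb/c at 18 h, Camp, and 4 lower over the list alone (mean -0.78, camera adjusted p = 0.0024, adjusted p = 0.44 with an estimated correlation). Camera also called this list lower at 18 h than at 4 h, a call lost with normexp (mean -0.90, adjusted p = 0.0667) and with an estimated correlation. Relative to C57BL6 mock the list mean went from -1.50 to -2.40 in Balb/c and from -0.285 to -0.52 in C57BL6. Stromal markers had 0 of 6 called and 3 lower over the list alone in C57BL6 at 18 h (mean -0.78, camera adjusted p = 0.0216, adjusted p = 0.42 with an estimated correlation, and 0.198 without C57BL6 mock replicate 1), and Pdgfrb was higher in untreated Balb/c cells by 3.55 ± 0.43 (adjusted p = 0.0028). Markers of T cells, B cells, erythroid cells and mast cells or basophils and the sex-linked genes had 0 called in any comparison, with the smallest camera adjusted p at 0.533, 0.0582, 0.305, 0.435 and 0.38.

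The 966 genes called between the untreated strains could in part come from probes that bind Balb/c transcripts less well because of sequence variants. Of the calls 47.5% were higher in Balb/c, which variants alone cannot give. Among genes called lower, 79.7% of 251 further probes were lower too (95% limits 74.3% to 84.2%), with a median of -0.60 against -1.33 for the tested probes. Among genes called higher 85.4% of 198 further probes agreed (95% limits 79.8% to 89.6%), with a median of 1.18 against 1.48, and 342 of the lower genes had no further probe to ask. Variants may thus account for some of the lower genes, and the arrays cannot tell which, while a difference between the strains in gene regulation stays open, since it was not tested apart from the probes.

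Slide and gene order were weighed for the same calls. With slide as a term 100% of the called genes kept their sign, the median size moved from 1.62 to 1.53 log2 and 382 of the 966 stayed called. These genes were called from the same arrays, and within a group slide varied only together with replicate. The slide term thus cannot settle whether slide gave the signs. Slide 2 held 1 array of each strain at 4 h of IL-4. Between them 97.5% of the called genes had the same sign, with a median of 1.28 log2, so most signs also appeared within a slide. Neighbouring genes were called together 1.74 times as often as in random draws (70 pairs against 40.2, permutation test, p = 1e-04, the smallest possible). The calls at 18 h of IL-4 gave 2.5 and 3.28 by the same count. Without neighbours of the same gene family the ratios were 1.54 for the strain calls and 1.89 and 2.08 for IL-4, so clustering may be a property of called genes in general. Whether inherited segments carry part of the strain difference stays open.

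Lower neutrophil markers in untreated Balb/c cells may come from fewer residual granulocytes in those cultures or from lower expression in the macrophages. With slide as a term the list mean was -1.91 (camera adjusted p = 4.86e-05), against -1.62 without it, which argues against a slide effect. The list call between the untreated strains did not hold with an estimated correlation. Of 22 further granulocyte genes, 11 were above background on both C57BL6 mock arrays, with a median of -1.83 (95% limits -2.07 to 0.34). Of these 11, 5 were above background on 0 of 2 Balb/c mock arrays, so the median is in part measured against background, and of the 4 above background on both, Ctsg was lower (-1.03) and Hp (0.52), Mmp25 (0.34) and Csf3r (1.28) were not. The arrays cannot tell the explanations apart, and a strain difference in expression stays open.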
